A study of Mus musculus with 8 samples.

How the data were processed

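The series measured the bacterial makeup of stool from 8 female mice, each with its own animal number in the labels. Of these, 4 lacked Gpr15l (genotype given as ko, called knockout here) and 4 were controls (genotype given as wt). Gpr15l encodes a secreted ligand of the chemoattractant receptor GPR15. The labels describe knockouts and controls as littermates that shared cages for 8 weeks before stool was taken. They give no cage, litter or sequencing run for any mouse. Animals are named here knockout 1 to 4 and control 1 to 4. These numbers follow the order of deposit and pair no knockout with a control.

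Per the labels' protocols, stool DNA was extracted with a Qiagen stool kit and the V4 region of the 16S ribosomal RNA gene was amplified from 10 ng of DNA. The primers sit at positions 515 and 806 of that gene, and the reaction ran for 25 cycles. Barcoded products were pooled in equal molar amounts and read from both ends on a MiSeq at 151 bases per end. The deposited table holds counts of reads per amplicon sequence variant (ASV), a distinct read sequence inferred by DADA2, as the table's name states. The submitters' processing notes name R 4.5.1 and limma without saying what each did. The read filters, the chimera step and the taxonomy database are not given in the sources used here. Each ASV is identified in the table only by a taxonomy string, so ASV numbers in the text are the position of the variant in the deposited table. No sequences were used here, and distances based on a tree of sequences were not computed.

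The table has 3697 ASVs, in 2 styles of taxonomic names. All 914504 reads of these 8 mice lay in 434 of the 1903 ASVs with newer phylum names, and the 1794 ASVs with older names had 0 reads here. No column of another sample was present. The 434 ASVs carried 111 distinct taxonomy strings, and 376 shared a string with at least 1 other ASV. Counts were summed to 105 genera, 53 families and 12 phyla. ASVs without a genus name (199, with 56.6% of reads) were kept as unnamed members of their family or order. A single ASV assigned to mitochondria held 302 reads and one assigned to eukaryotes held 2 reads. Both stayed in the totals.

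Total counts ran from 129792 to 226654 in knockouts and from 38578 to 122026 in controls. PCR reads carry no molecular identifiers, so intervals and floors cover counting error only. A share printed for a single mouse had a 95% Wilson interval reaching at most 0.490 percentage points to either side, and at most 0.103 points for shares under 1%. A count of 0 allows a share of up to 3 reads of the total, which was 0.00132% in knockout 1 and 0.00778% in control 2.

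Before the data were examined, the tests, the taxon lists, the taxa to be named and most alternatives were fixed. ASVs, genera and families with at least 10 reads in at least 3 mice were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors and the robust quasi-likelihood test. Adjusted p-values are Benjamini-Hochberg values over all units tested at that level, with a threshold of 0.05. Log2 fold changes are knockout over control, with the standard error of the fit. TMM factors ran from 0.52 in knockout 1 to 1.38 in knockout 3, so the factors moved fold changes. The median log2 fold change of the ASVs tested was 0.19 with TMM and -0.33 with total reads only, of genera 0.056 and -0.33, and of families -0.0024 and -0.40. Fold changes are to be read against these medians.

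Phyla with a mean share of at least 0.1% and 12 fixed taxon lists were compared by the difference of mean shares of reads, with two-sided exact permutation tests over the 70 assignments of 8 mice to 4 and 4. The smallest p of this test is 0.0286. After Benjamini-Hochberg adjustment no phylum could pass unless at least 4 of the 7 tested reached that p, and no list unless 7 of the 11 detected did. With exactly 4 phyla the adjusted p would equal the threshold itself. Alpha diversity was computed after rarefying each library to 38578 reads, as the mean of 100 draws. Community composition was compared by PERMANOVA on Bray-Curtis distances of ASV shares, exact over the 35 distinct splits into 4 and 4. These used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. All p-values in the text, those of edgeR too, treat the 8 mice as independent. Mice that share a cage or litter may not be, and without such labels this could not be modelled.

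Taxa are named by a rule. It takes each ASV, genus or family past the threshold, the 10 ASVs, 10 genera and 10 families of highest mean share, and each phylum of at least 0.1%. It also takes each detected genus of the lists, and the 5 ASVs of smallest unadjusted p, since no ASV passed. Other taxa in the text were chosen after their values were seen.

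Alternatives fixed beforehand were DESeq2 1.42.0 with poscounts size factors, limma-voom (limma 3.58.1), total-read scaling, TMMwsp, and centred log-ratios with a pseudocount of 0.5. Others were no low-count filter, 10 reads in at least 5 mice, rarefied counts, other indices and distances, and leaving out each mouse in turn. Added after the data were seen were log2 library size as a covariate, Bray-Curtis distances on rarefied counts, and leaving out knockout 1 and control 2 together. Weighted and unweighted UniFrac, also planned, were not run without sequences.

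The tests were tried on simulated data drawn from the real means and library sizes with 4 mice per group. At the ASV level the edgeR test recovered 2% of 4-fold and 21.8% of 16-fold changes among 265 ASVs, at the genus level 6.67% and 55.8% among 76 genera, and at the family level 10% and 50% among 39 families. Among simulated calls, 3.06% of ASVs, 7.41% of genera and 7.69% of families were false. Here each unit was drawn independently from the count model that edgeR fits, with changes up or down at random. These rates need not hold in real data where related ASVs shift together or depth follows genotype. PERMANOVA fell below the threshold in 0.5% of 200 simulations without an effect and in 93% of those with 100 ASVs shifted. In the PERMANOVA simulations each ASV varied between mice independently, by an amount set beforehand and not taken from the data. All 100 were shifted upward in knockouts, so the 93% is not the power of the test in these mice. The assay reads bacterial DNA and gives no value for the Gpr15l gene, so the genotype labels could not be checked against it.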

Results

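Stool was compared between 4 Gpr15l knockout mice and 4 control mice, all female, after 8 weeks in shared cages. The question was whether littermates that differ in Gpr15l carry different gut bacteria when they live together. Sequencing of the 16S V4 region gave 914504 reads in 434 ASVs. Of these, 123 ASVs were seen in all 8 mice and held 84.8% of reads, and 114 were seen in 1 mouse. Muribaculaceae, a family of carbohydrate-degrading Bacteroidota common in the mouse gut, was the most abundant family, with a mean share of 44.7% over all mice. Lachnospiraceae followed with 12.0%, Rikenellaceae with 10.7% and Bacteroidaceae with 7.46%. Depth differed between the genotypes. Knockout libraries held 161504 ± 44242 reads and control libraries 67122 ± 37701 (SD, n = 4 each), and every knockout library exceeded the deepest control library (two-sided exact permutation p = 0.0286).

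Mycoplasmataceae and Rikenellaceae were lower in knockout mice. Mycoplasmataceae, which are bacteria without a cell wall, made up 0.0762% ± 0.0402 of reads in knockouts and 1.45% ± 1.01 in controls (SD, n = 4 each). This is a 14.4-fold lower fitted level (log2 fold change -3.85 ± 0.72 SE, edgeR adjusted p = 0.0166). Rikenellaceae, a family of anaerobic Bacteroidota, made up 2.99% ± 2.02 in knockouts and 18.4% ± 14.6 in controls, a 5.11-fold lower fitted level (log2 fold change -2.35 ± 0.53 SE, edgeR adjusted p = 0.0301). In both families all 4 knockouts lay below all 4 controls. Rikenellaceae reached 40.0% (95% Wilson interval 39.5 to 40.5%) in control 2 and between 8.15% and 13.5% in the other controls.

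**Figure D1:**
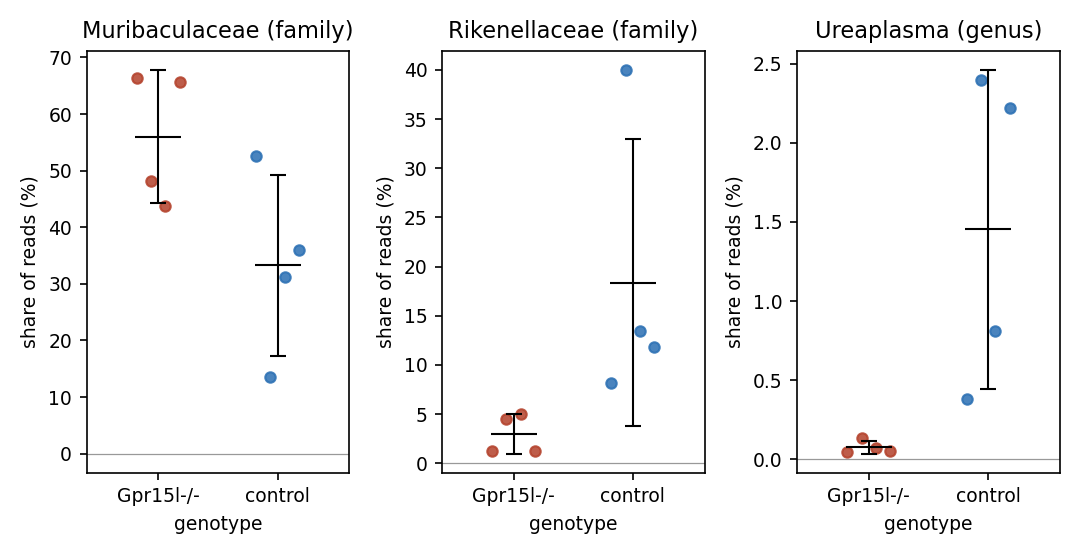
Share of reads in percent (vertical axes, linear) of Muribaculaceae, Rikenellaceae and the genus Ureaplasma in each of 4 knockout and 4 control mice. Points are mice, horizontal bars are means and error bars are 1 SD. Rikenellaceae and Ureaplasma lie lower in all 4 knockouts than in any control, whereas the Muribaculaceae values of the genotypes overlap.

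The 2 families were the ones past the threshold among 39 tested with edgeR, where 5 had an unadjusted p below 0.05. At the genus level, 1 of 76 passed. Ureaplasma, a genus that splits urea and held all the Mycoplasmataceae reads, fell in knockouts by 3.79 ± 0.70 on the log2 scale (edgeR adjusted p = 0.0277). Of its 4771 reads, 4769 belonged to a single variant, ASV2482, which did not pass over all ASVs (edgeR adjusted p = 0.162). The family and genus calls therefore rest on nearly the same reads of 1 variant. Alistipes, a bile-tolerant genus that made up nearly all Rikenellaceae reads, had a mean share of 2.92% ± 2.02 in knockouts and 18.3% ± 14.5 in controls. Its log2 fold change of -2.38 ± 0.58 missed the threshold (edgeR adjusted p = 0.0920). Leaving out any 1 knockout ended both family calls, with adjusted p from 0.0765 to 0.101 for Mycoplasmataceae and from 0.0812 to 0.183 for Rikenellaceae, and ended the Ureaplasma call, which was also lost without control 2 or control 4. Centred log-ratios with limma also ended them (adjusted p = 0.126, 0.388 and 0.197), as did leaving out knockout 1 and control 2 together (0.118, 0.124 and 0.184). Rikenellaceae was also lost without a filter (0.0527) and with 10 reads in 5 mice (0.0508), and Ureaplasma with limma-voom (0.0590). With log2 library size as a covariate, added after the data were seen, the Rikenellaceae log2 fold change was -1.53 ± 0.77 (edgeR adjusted p = 0.914) and that of Ureaplasma -4.23 ± 0.94 (adjusted p = 0.134).

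None of the other abundant families passed the edgeR test. Sutterellaceae, a family of Pseudomonadota, made up 6.45% ± 3.28 of reads in knockouts and 2.51% ± 1.50 in controls (log2 fold change 2.21 ± 0.82, adjusted p = 0.240). These reads were almost entirely Turicimonas, at 6.45% ± 3.28 and 2.51% ± 1.50 (log2 fold change 2.30 ± 0.80, adjusted p = 0.326). An unnamed family of the Clostridia vadinBB60 group had means of 0.233% ± 0.208 in knockouts and 1.46% ± 1.76 in controls (adjusted p = 0.176). All 4 knockouts lay below all 4 controls in this family too, so that 3 of 39 families were separated without overlap, in each case lower in knockouts. At the genus level 4 of 76 were, also lower in knockouts, namely Ureaplasma, Alistipes, Ligilactobacillus and the unnamed Clostridia vadinBB60 group. Chance separates 2.86% of taxa, counting both directions. Mean shares in knockouts and controls were 10.1% and 13.8% for Lachnospiraceae, 7.12% and 7.81% for Bacteroidaceae, 3.15% and 6.24% for Helicobacteraceae, and 3.66% and 3.26% for Prevotellaceae. They were 2.92% and 3.75% for Oscillospiraceae and 0.895% and 1.56% for Tannerellaceae. Adjusted p-values of these 6 families were 0.738 or higher.

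Among the abundant genera, Bacteroides made up 7.12% ± 1.92 of reads in knockouts and 7.81% ± 3.57 in controls. Prevotellaceae UCG-001 made up 3.66% ± 1.30 and 3.26% ± 0.787, and Lachnospiraceae NK4A136 group 3.21% ± 2.18 and 3.58% ± 1.37. Butyribacter made up 2.58% ± 1.78 and 3.80% ± 1.98, Parabacteroides 0.841% ± 0.534 and 1.52% ± 0.941, and unnamed Lachnospiraceae 3.16% ± 1.93 and 4.51% ± 2.42. None of these passed the edgeR test, with adjusted p of 0.788 or higher. Helicobacter, a genus that lives in intestinal mucus, made up 3.15% ± 2.56 of reads in knockouts and 6.24% ± 0.649 in controls. Its fitted log2 fold change with TMM factors was 0.047 ± 0.77 (adjusted p = 0.989), and it turned to -0.98 with total reads only, -0.70 with limma-voom and with centred log-ratios, -2.24 with the covariate and -1.70 without knockout 1, among other alternatives.

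Single ASVs of Muribaculaceae were mostly higher in knockouts, without any passing the test over all ASVs. Of 46 Muribaculaceae ASVs tested, 43 had a fitted log2 fold change above 0, with a median of 1.90 against 0.19 for all 265 ASVs tested. With total reads only, the medians were 1.37 and -0.33. At an unadjusted p below 0.05, 21 of the 46 were higher in knockouts and 0 were lower. The number higher was 11 with total reads only, 14 with DESeq2, 12 without control 2 or control 3, 13 without control 4 and 10 without knockout 1 and control 2 together. Adjusted over the list alone, which was fixed before the data were examined, 11 of the 46 passed, all higher in knockouts. This number was 0 in 14 of 18 alternatives, among them DESeq2, limma-voom, total reads only and leaving out any 1 mouse except knockout 2 (2 passed) or control 1 (8 passed). Without a filter it was 6, and with 10 reads in 5 mice 5. With log2 library size as a covariate 0 of the 46 had an unadjusted p below 0.05, with a median log2 fold change of 0.92 against 0.50 for all ASVs.

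Over all ASVs, the edgeR test called 0 of 265, with 34 at an unadjusted p below 0.05, 28 of them higher and 6 lower in knockouts. DESeq2 called 1, limma-voom 0 and centred log-ratios with limma 0. The ASV that DESeq2 called was ASV2482, assigned to Ureaplasma, which had the smallest p with edgeR too (log2 fold change -3.78 ± 0.77, adjusted p = 0.162). The next 4 by p were Muribaculaceae with no genus name, each with an edgeR adjusted p of 0.228. ASV2745 made up 1.92% ± 1.94 of reads in knockouts and 0.230% ± 0.102 in controls, and ASV2779 made up 1.50% ± 0.424 and 0.581% ± 0.206. ASV2699 made up 1.39% ± 1.00 and 0.371% ± 0.108, and ASV2714 made up 0.895% ± 0.300 and 0.297% ± 0.168.

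The most abundant ASV was ASV2705 of Muribaculaceae, with 7.13% ± 2.50 of reads in knockouts and 8.25% ± 3.71 in controls (SD, n = 4 each). ASV2829, assigned to Alistipes, made up 1.18% ± 1.10 in knockouts and 11.6% ± 10.8 in controls (edgeR adjusted p = 0.431). It had 0 reads in knockout 1, which allows a share of up to 0.00132%, and 27.3% (95% Wilson interval 26.8 to 27.7%) in control 2. Another Alistipes variant, ASV2822, made up 0.720% ± 0.388 and 4.46% ± 4.25. The Muribaculaceae variants ASV2795, ASV2671, ASV2791 and ASV2677 had means of 5.56%, 5.75%, 4.93% and 3.28% in knockouts and 2.95%, 1.81%, 2.50% and 2.55% in controls. ASV3458 of Turicimonas made up 5.64% ± 2.86 and 2.28% ± 1.41, and ASV2530 of Prevotellaceae UCG-001 made up 3.66% ± 1.29 and 3.26% ± 0.787. ASV2881 of Helicobacter made up 1.25% ± 0.395 and 4.07% ± 1.65. Adjusted p-values of these ASVs with edgeR were 0.228 or higher.

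Bacteroidota and Bacillota held most reads in both genotypes. Bacteroidota made up 70.8% ± 7.19 of reads in knockouts and 64.6% ± 8.68 in controls, and Bacillota 18.4% ± 11.4 and 25.2% ± 9.87 (SD, n = 4 each). Pseudomonadota had means of 6.74% ± 3.07 and 2.72% ± 1.45, and Campylobacterota, here all Helicobacter, 3.15% ± 2.56 and 6.24% ± 0.649. No phylum passed the two-sided exact permutation test after adjustment. The smallest p-values were 0.0571 for Pseudomonadota and 0.114 for Campylobacterota, both with an adjusted p of 0.400. Thermodesulfobacteriota made up 0.519% and 0.816%, Deferribacterota 0.156% and 0.223%, and Actinomycetota 0.194% and 0.146%. When the counts summed per phylum were tested with edgeR instead, Pseudomonadota passed (log2 fold change 2.10 ± 0.68, adjusted p = 0.0265).

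**Figure D2:**
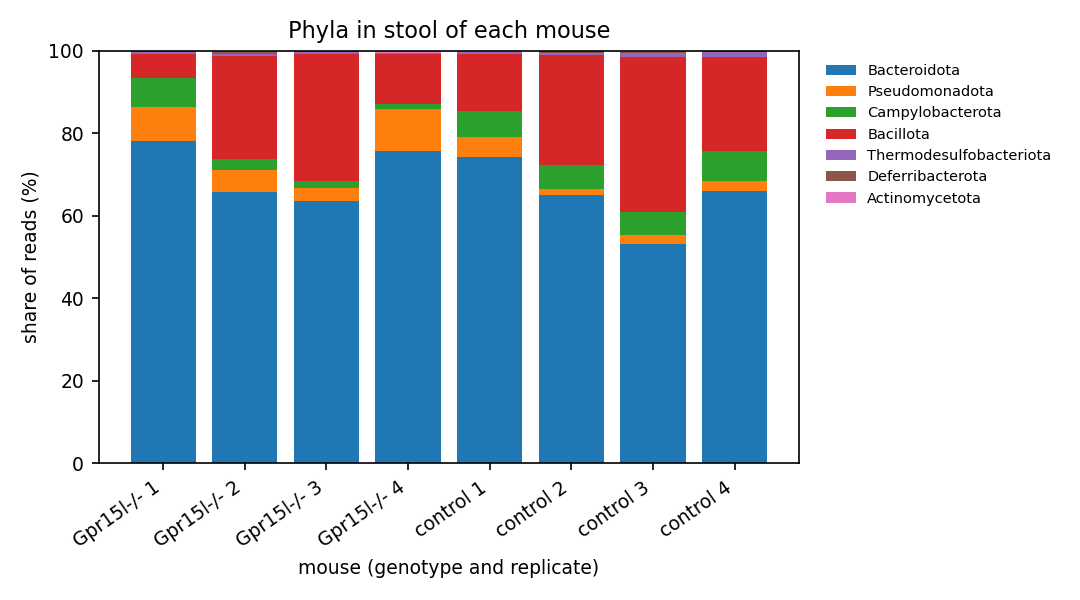
Stacked bars of the share of reads in percent (vertical axis from 0 to 100) of the 7 phyla with a mean share of at least 0.1%, one bar per mouse. Bacteroidota is the largest part of each bar, from 53.2% in control 3 to 78.1% in knockout 1, and Pseudomonadota ranges from 1.39% in control 2 to 10.1% in knockout 4.

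Of the 12 taxon lists fixed beforehand, 11 had reads and none passed the two-sided exact permutation test after adjustment. The list of reagent and environmental genera had 0 reads. Muribaculaceae as a whole made up 56.0% ± 11.8 of reads in knockouts and 33.3% ± 16.0 in controls (exact p = 0.0857, adjusted p = 0.419), with ranges of 43.7 to 66.4% and 13.6 to 52.5%. The part without a genus name made up 54.8% and 32.5%, and Muribaculum 1.23% and 0.849%. Lactic acid bacteria and bifidobacteria made up 0.0821% ± 0.0254 and 0.143% ± 0.0366 (exact p = 0.0571, adjusted p = 0.419). Ligilactobacillus, the largest part of this list, had means of 0.0427% and 0.0908%, and Lactobacillus 0.0296% and 0.0442%. Streptococcus had reads in 4 mice and Bifidobacterium in 1. The list matched genus names, so Lactobacillaceae reads without a genus name, at 0.287% and 0.360%, lay outside it. Lactobacillaceae as a whole made up 0.360% ± 0.224 and 0.495% ± 0.184 (exact p = 0.400). Over all ASVs tested, 0 of 46 Muribaculaceae ASVs and 0 of 2 ASVs of the lactic acid bacteria list passed. Adjusted over each list alone, 11 and 0 did. The 11 fell to 0 with DESeq2, limma-voom and total reads only, among other alternatives.

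Candidatus Arthromitus, the segmented filamentous bacteria that attach to the intestinal wall and induce Th17 cells, made up 0.0437% ± 0.0519 of reads in knockouts and 0.0370% ± 0.0359 in controls (exact p = 0.800). The mucus-associated genera made up 7.29% ± 1.99 and 8.03% ± 3.51 (exact p = 0.857). Within them Mucispirillum made up 0.156% and 0.223%. Akkermansia was seen in knockouts 1, 2 and 4 (47, 74 and 2 reads) at up to 0.0532%, and had 0 reads in every control. A count of 0 allows up to 0.00246% in control 4 and up to 0.00778% in control 2. The 0.00133% of knockout 4 lies below both, so the controls could not show such a share. The Th17- or Treg-linked genera, here Bacteroides, Helicobacter and Candidatus Arthromitus, made up 10.3% ± 3.60 and 14.1% ± 4.18 (exact p = 0.286). Helicobacter alone had an exact p of 0.114, with knockout 1 at 6.89% and the other knockouts between 1.34% and 2.65%. No ASV or genus of these 4 lists passed over all units tested or adjusted over the list alone.

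The butyrate-producer genera of the fixed list made up 4.73% ± 3.04 of reads in knockouts and 5.56% ± 2.13 in controls (exact p = 0.714). They were mostly the Lachnospiraceae NK4A136 group, with Oscillibacter at 0.901% and 1.06%, Intestinimonas at 0.336% and 0.463%, and Roseburia at 0.205% and 0.351%. The Eubacterium xylanophilum, siraeum, ventriosum and brachy groups, matched by the leading part of their names, each had means below 0.1% in both genotypes. Butyribacter (2.58% and 3.80%) and Agathobaculum (0.209% and 0.159%) were not on the list, so its total does not cover them. Of 40 butyrate-producer ASVs tested, 21 had a log2 fold change above 0 and 19 below 0, and 0 passed over all ASVs or adjusted over the list alone. Bile-acid and sulfate related genera made up 0.114% ± 0.0321 and 0.121% ± 0.0406 (exact p = 0.8286), with the sulfate reducer Desulfovibrio at 0.102% and 0.116% and Bilophila at 0.0120% and 0.00554%. Desulfovibrionaceae reads without a genus name, at 0.405% and 0.694%, lay outside this list. Desulfovibrionaceae as a whole made up 0.519% ± 0.125 and 0.816% ± 0.432 (exact p = 0.257). Escherichia-Shigella, the member found of the facultative Enterobacterales, made up 0.0114% and 0.0117% (exact p = 1). Staphylococcus and Corynebacterium, the skin genera found, had 884 reads together, of which 852 were Staphylococcus in control 3. Mitochondrial reads made up 0.0329% ± 0.0231 and 0.0482% ± 0.0255 (exact p = 0.343).

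The share of the variation in Bray-Curtis distances between the 8 communities that lay between genotypes (R2) was 0.295. Of the 35 splits of the mice into 4 and 4, 2 gave an R2 as large (exact p = 0.0571), and the other one gave 0.307. Knockouts 2 and 3 had the most similar communities, at a distance of 0.226, and control 2 and knockout 1 the least similar, at 0.694. The nearest community to knockout 1 was that of control 1. The mean distance was 0.386 within knockouts, 0.404 within controls and 0.461 between genotypes, and the spread within genotypes differed by -0.018 (two-sided exact permutation p = 0.857). On square roots of shares, which weight abundant ASVs less, R2 was 0.252, the highest of the 35 splits (exact p = 0.0286). R2 was also the highest of the splits without control 1 (0.392) or without control 3 (0.311). It was not the highest with Jaccard distances on presence (0.167, exact p = 0.257), Aitchison distances (0.170, exact p = 0.200), genus shares (0.387, exact p = 0.0857) or without control 2 (0.259, exact p = 0.143).

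**Figure D3:**
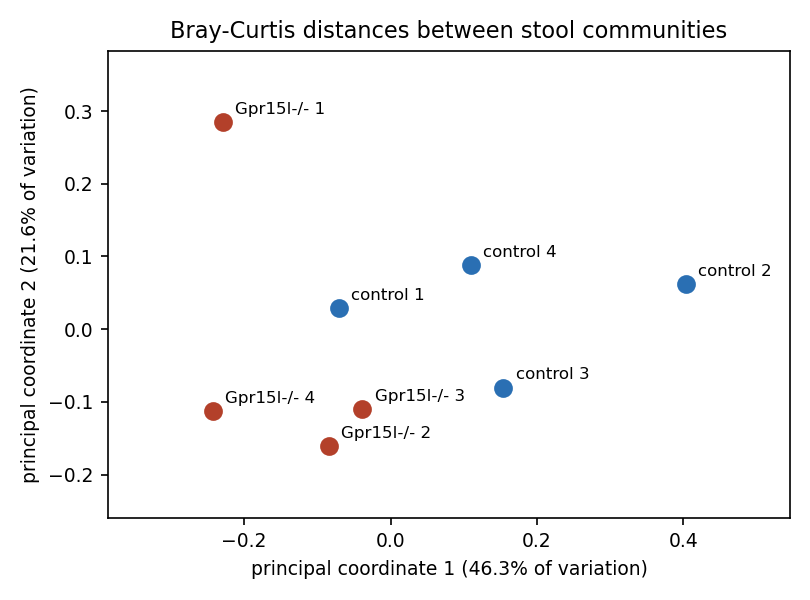
Principal coordinates of Bray-Curtis distances between ASV shares of the 8 mice, with coordinate 1 (46.3% of variation) on the horizontal axis and coordinate 2 (21.6%) on the vertical axis. Each point is a mouse, named by genotype and replicate. Knockouts lie between -0.243 and -0.0386 on coordinate 1 and controls between -0.0708 and 0.403, so the ranges overlap, and knockout 1 lies apart on coordinate 2 at 0.285.

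Diversity at equal depth differed between the genotypes by less than the spread between mice. The Shannon index was 4.11 ± 0.40 in knockouts and 4.01 ± 0.32 in controls (SD, n = 4 each, two-sided exact permutation p = 0.714). At 38578 reads, 261 ± 43.1 ASVs were observed in knockouts and 238 ± 31.5 in controls (exact p = 0.429). The 10 most abundant ASVs of a mouse held 46.9% ± 11.05 of reads in knockouts and 48.9% ± 8.49 in controls (exact p = 0.771). No ASV was present in all 4 mice of one genotype and absent from the other at equal depth, while other splits gave up to 3 such ASVs. With presence in at least 3 of 4 mice of one genotype, 8 ASVs were found in knockouts alone and 1 in controls alone, a total that 3 of 35 splits reached (exact p = 0.0857).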

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

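The tests of library size on the 2 families, of reads taken up by Muribaculaceae, of missing ASVs, of scaling and of other splits on numbers of calls were chosen after the results were seen. The tests of library size and of other splits on Muribaculaceae ASVs were set out before their values were seen.

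Some mice lay far from the other 3 of their genotype, with a gap to the nearest of them above Dixon's 95% critical share of the group's range. This occurred 23 times in 158 groups examined. In 11 of the 23, 1 mouse had reads and the other 3 had 0, where any read gives the largest possible gap, so these 11 show presence in 1 mouse and no more. The other 12 came from 144 groups with reads in 2 or more mice, where chance alone would give about 1 in 20 for normally distributed values. The groups are not independent, because a genus, its family and its ASVs share reads.

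Control 2 stood apart in Rikenellaceae, with 40.0% of reads against 8.15 to 13.5% in the other controls, and in Alistipes, with 39.8% against 8.11 to 13.4%. It also had 4.10% of the Clostridia vadinBB60 group, against 0.498 to 0.662%. Without control 2 the Rikenellaceae log2 fold change was -1.72 ± 0.36 and stayed past the threshold (edgeR adjusted p = 0.0291). Over the 18 alternatives the adjusted p ran from 0.00817 with DESeq2 to 0.914 with the library size covariate in edgeR.

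Knockout 1 stood apart in 6 taxa. It had 1.73% of ASV2530, of Prevotellaceae UCG-001 and of Prevotellaceae, which share these reads, against 4.19 to 4.46% in the other knockouts. It had 4.83% of ASV2745 against 0.804 to 1.08%, and 2.89% of ASV2699 against 0.801 to 0.963%. It was also the one mouse with Bifidobacterium, at 0.0344% (78 reads), where the other libraries had 0 reads.

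Control 3 had 1.41% Staphylococcus, which is also its share of the Gram-positive skin genera, where the other controls had 0 reads, and 0.621% Roseburia against 0.241 to 0.275%. Knockout 2 had 0.0208% Staphylococcus, 0.00216% Corynebacterium and 0.0230% of the skin genera together, with 0 reads in the other knockouts. Control 1 had 0.889% of ASV2779 against 0.451 to 0.494%. Knockout 3 had 0.0609% Lactobacillus against 0.0180 to 0.0201%. The Eubacterium brachy group was seen in knockout 3 at 0.0116% and control 4 at 0.00328%, and the Eubacterium ventriosum group in knockout 3 at 0.0963% and control 3 at 0.0182%. Streptococcus was at 0.00465% in knockout 4 with 0 reads in the other knockouts, and at 0 reads in control 4 with 0.00991 to 0.0106% in the other controls.

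Mycoplasmataceae and Rikenellaceae were lower in knockouts, whose libraries were also deeper. With log2 library size as a covariate the Mycoplasmataceae log2 fold change was -4.48 ± 0.92 and at equal depth it was -3.67, both past the threshold (edgeR adjusted p = 0.0447 and 0.0350). Over all 18 alternatives the adjusted p ran from 1.09e-05 with DESeq2 to 0.126 with centred log-ratios and limma. The same reads tested as the genus Ureaplasma did not pass with the covariate (-4.23 ± 0.94, edgeR adjusted p = 0.134). At neither level did the fold change shrink with the covariate. For Rikenellaceae the values with the covariate and at equal depth were -1.53 ± 0.77 and -2.32 (edgeR adjusted p = 0.914 and 0.0453). For both families library size cannot be told apart from genotype, because every knockout library is deeper than every control library. Outside Muribaculaceae reads, the log2 ratio of mean shares was -3.61 for Mycoplasmataceae and -2.03 for Rikenellaceae, so reads taken up by Muribaculaceae alone do not account for them. The two-sided exact permutation p was 0.0286 for both, the smallest possible. It adds no support, because every knockout already lay below every control in both families before these reads were removed. Genotype, cage and litter stay open, since the labels tie no mouse to a cage or litter.

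The number of families called (2) was reached by 1 of the 35 splits, the real one, with 0 calls in the highest of the others, and the number of genera called (1) likewise by 1 of 35, with 0 in the highest other. A share of 1 in 35 (0.0286) is the smallest this comparison can give, and the comparison was chosen after the calls were seen. It therefore does not exclude chance for these numbers of adjusted calls, which count the same reads once at each level for Ureaplasma. The splits were counted for edgeR with TMM factors alone. Both numbers are 0 without any 1 knockout, with centred log-ratios and without knockout 1 and control 2 together, and the number of genera is also 0 with limma-voom, with the covariate and without control 2 or control 4. In these settings the comparison would decide nothing. Chance cannot be excluded either for the numbers at an unadjusted p below 0.05, which were 5 families and 6 genera in the real split. The others gave up to 8 and 11, with 6 of 35 splits reaching the real number at each level. For ASVs the real split called 0, a number that all 35 splits reach whatever the data (highest other 0), so this comparison decides nothing. At an unadjusted p below 0.05 the real split had 34 ASVs and the highest other 32.

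Knockout 1 lacked 18 ASVs that all 7 other mice carried, which together held a mean of 12.2% of reads in those mice, while control 2 lacked 12 with 1.31%. Library size does not account for it: knockout 1 is the deepest library, and at the lowest share in another mouse a median of 46.3 reads per missing ASV was due. Replacement by a variant of the same genus that no other mouse carried was seen for 1 of the 18. Variants shared with other mice were not examined as replacements. The largest of the missing was the Alistipes variant ASV2829, at a mean of 7.28% in the other mice, and Sporosarcina, Jeotgalicoccus and Peptococcus were each at 0 reads. A different cage or litter history may explain it as a hypothesis, and no biological explanation was tested because the labels give none that singles out this mouse.

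Of 46 Muribaculaceae ASVs, 21 were higher in knockouts at an unadjusted p below 0.05 in the edgeR fit, 0 were lower and 0 passed over all ASVs. The median log2 fold change of the 46 was 1.37 with total reads only, against -0.33 for all ASVs, so TMM scaling is not the source of the direction. With log2 library size as a covariate the median was 0.92, against 0.50 for all ASVs, and library size cannot be told apart from genotype here. The number at an unadjusted p below 0.05 was 11 with total reads only, 12 without control 2 or control 3 and 13 without control 4. Of the 35 splits, 2 gave at least the real number of 21 such ASVs in one direction, and the other one, with control 1 in the place of knockout 3, gave 23, so chance cannot be excluded. A genotype effect on this family is a hypothesis that these 8 mice leave open.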

How the results depend on the processing

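Alternatives with log2 library size as a covariate, with Bray-Curtis distances on rarefied counts and without knockout 1 and control 2 together were chosen after seeing the data, and the cause of each change below was not tested except where fewer mice or units are the change itself. No paired analysis was possible because replicate numbers follow the order of deposit. Weighted and unweighted UniFrac were not run. The difference in observed ASVs kept its direction in all 12 alternatives, but ran from 5.94 to 39.5 without 1 mouse (two-sided exact permutation p from 0.229 to 0.800). The alternative on all reads was not at equal depth, and the knockout libraries are deeper. No taxon list passed in any of 12, but the exact test could pass a list only if 7 of the 11 reached its smallest p, so this says little about stability. EdgeR on summed counts, which has no such limit, gave 0 too. With 4 mice per genotype at these depths, simulated 4-fold changes were recovered in 10% of cases or fewer, and neither depth nor the number of mice was varied in the simulation.

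With DESeq2, 1 ASV, 2 genera (Ureaplasma and Alistipes) and 3 families passed, the third family being Atopobiaceae, higher in knockouts (adjusted p = 0.0348). Total reads only gave 1 ASV. Genera numbered 0 with limma-voom, centred log-ratios, the covariate and without knockout 1 and control 2, 2 when rarefied, and from 0 to 1 when 1 mouse was left out. Families numbered 0 with centred log-ratios and without knockout 1 and control 2. They numbered 1, in each case Mycoplasmataceae, without a filter, with 10 reads in 5 mice and with the covariate, and from 0 (without any 1 knockout) to 2 (without any 1 control). With edgeR on summed counts 1 phylum passed. R2 was 0.252 on square roots, 0.167 with Jaccard and 0.170 with Aitchison distances, 0.387 on genus shares and 0.293 on rarefied counts, and ran from 0.259 to 0.392 without 1 mouse. It was the highest of the 35 splits on square roots and without control 1 or control 3, and not in the other alternatives with 35 splits. The spread difference turned to 0.0125 on square roots, 0.0358 with Jaccard and 8.00 with Aitchison distances, and ran from -0.103 to 0.0451 without 1 mouse. The Shannon difference ran from -0.0474 to 0.221 without 1 mouse. Genotype-exclusive ASVs numbered 1 at 10 reads without rarefaction, 9 with 3 of 4 mice, 5 without knockout 1 and control 2, and 0 to 3 without 1 mouse.

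Among 69 named taxon values, 36 kept their sign in every alternative, and the other 33, of which 0 were past the threshold, changed sign in at least 1. The following log2 fold changes turned. With total reads only they were ASV2705 (-0.21), Bacteroides (-0.13), Helicobacter (-0.98), Lachnospiraceae NK4A136 group (-0.16), Bacteroidaceae (-0.13), Helicobacteraceae (-0.98), Desulfovibrio (-0.18), Escherichia-Shigella (-0.046), Mucispirillum (-0.51), Oscillibacter (-0.24) and the Eubacterium xylanophilum group (-0.40). With the library size covariate they were ASV2705 (-0.73), Bacteroides (-0.74), Helicobacter (-2.24), Bacteroidaceae (-0.97), Helicobacteraceae (-2.58), Bilophila (-2.04), Desulfovibrio (-0.086), Lactobacillus (0.89), mitochondrial reads (1.15), Roseburia (0.15) and the Eubacterium siraeum group (0.70). Without knockout 1 and control 2 they were ASV2705 (-0.39), Bacteroides (-0.27), Helicobacter (-1.66), Butyribacter (0.033), Lachnospiraceae (0.12), Bacteroidaceae (-0.032), Helicobacteraceae (-1.46), Oscillospiraceae (0.090), Bilophila (-0.33), Escherichia-Shigella (-0.11) and Mucispirillum (-0.18).

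With limma-voom these were Helicobacter (-0.70), Helicobacteraceae (-0.80), Oscillospiraceae (0.0012), Intestinimonas (0.028), Lactobacillus (0.0997), mitochondrial reads (0.19) and Mucispirillum (-0.26). With TMMwsp they were Helicobacter (-0.013), Mucispirillum (-0.019), Oscillibacter (-0.10) and the Eubacterium xylanophilum group (-0.089). With centred log-ratios they were Helicobacter (-0.70), Helicobacteraceae (-0.74), Oscillospiraceae (0.082), Intestinimonas (0.13) and Mucispirillum (-0.27). With rarefied counts they were Helicobacter (-0.095), Oscillospiraceae (0.058), Lactobacillus (0.14), Mucispirillum (-0.089), Oscillibacter (-0.11) and the Eubacterium xylanophilum group (-0.078). Without a filter it was Helicobacteraceae (-0.074), with DESeq2 Oscillospiraceae (0.12) and the Eubacterium xylanophilum group (-0.023), and with 10 reads in 5 mice Oscillospiraceae (0.099) and Intestinimonas (0.015). With edgeR on summed counts they were Deferribacterota (0.049), mucus-associated genera (0.45), butyrate producers (0.15), bile-acid and sulfate related genera (0.45), Enterobacterales (0.39) and Th17- or Treg-linked genera (0.24). On log2 shares, the difference turned for segmented filamentous bacteria (-0.0708) and Enterobacterales (0.0176), and without knockout 1 and control 2 it was 0.00406 points for bile-acid and sulfate related genera.

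When 1 mouse at a time was left out, log2 fold changes crossed 0 for ASV2705 (-0.11 to 0.74), Bacteroides (-0.28 to 0.86), Helicobacter (-1.70 to 0.40), unnamed Lachnospiraceae (-0.34 to 0.011), Parabacteroides (-1.21 to 0.058), Lachnospiraceae (-0.30 to 0.013), Bacteroidaceae (-0.024 to 0.84), Helicobacteraceae (-1.47 to 0.47), Oscillospiraceae (-0.17 to 0.21) and Tannerellaceae (-0.96 to 0.094). They also did for Bilophila (-0.15 to 4.11), Candidatus Arthromitus (-0.86 to 1.90), Escherichia-Shigella (-0.19 to 0.77), Intestinimonas (-0.32 to 0.14), Lactobacillus (-0.44 to 0.18), mitochondrial reads (-0.55 to 0.16), Mucispirillum (-0.54 to 0.45), Oscillibacter (-0.041 to 0.11) and the Eubacterium xylanophilum group (-0.37 to 0.36). Share differences in percentage points crossed 0 for Actinomycetota (-0.0221 to 0.0945), segmented filamentous bacteria (-0.0173 to 0.0238), mucus-associated genera (-1.95 to 0.861), butyrate producers (-1.74 to 0.210), bile-acid and sulfate related genera (-0.0233 to 0.00846), Enterobacterales (-0.00491 to 0.00284) and skin genera (-0.463 to 0.00575).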

Other observations

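The taxa in this part were chosen after their values were seen, and no test here was planned. Helicobacter held 4 ASVs, and the 2 with the most reads differed in how they were spread over the mice. ASV2881 made up 1.25% ± 0.395 of reads in knockouts and 4.07% ± 1.65 in controls (SD, n = 4 each), with every knockout below every control (two-sided exact permutation p = 0.0286, the smallest possible, before adjustment over 4 ASVs). ASV2890 made up 5.06% of reads in knockout 1 and from 0.348 to 0.600% in the other knockouts, and from 0.256% in control 1 to 3.40% in control 3. ASV2893 and ASV2898 each stayed below 1% in every mouse. Helicobacter in knockout 1 was therefore mostly ASV2890, and in knockouts 2, 3 and 4 mostly ASV2881.

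Sporosarcina, Jeotgalicoccus, Aerococcus and Staphylococcus, Gram-positive genera of the Bacillota, held 9951 reads together and were unevenly spread over mice of both genotypes. Their summed share was 5.02% in control 3, 2.59% in knockout 2 and 2.14% in knockout 3. It was 0.438% in control 2, 0.162% in knockout 4, 0.152% in control 1 and 0.0270% in control 4. Knockout 1 had 0 reads of all 4 genera in 226654, which allows up to 0.00132%. Sporosarcina led in knockout 3 with 1.97%, and Jeotgalicoccus in control 3 with 1.85%.

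Knockout 1 carried 19 ASVs seen in no other mouse, with 0.979% of its reads. The largest were a Turicimonas variant, ASV3462, at 0.638%, and a Muribaculum variant, ASV2721, at 0.135%. Brachyspira, a genus of intestinal spirochaetes, was seen in this mouse alone, with 126 reads. Knockout 2 had more private ASVs, at 28, but with 0.331% of its reads. Depth limits these numbers, since knockout 1 is the deepest library. Its private variants from ASV3425 (17 reads, 0.00750%) downward lie below the 0.00778% that 0 reads allow in control 2. Their absence from that mouse is therefore not shown, whereas ASV3462 and ASV2721 lie far above this limit.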
